A study of Mus musculus with 9 samples.

How the data were processed

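Stranded mRNA libraries of C2C12 myotubes were measured in 9 samples: control, 200 µM palmitic acid, and 200 µM palmitic acid with 1000 µM carnitine, with 3 replicates each, per the labels. Groups were taken from the treatment label and replicate numbers from the sample titles. The kit marks strand, per the labels' protocols.

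The deposited table gives raw whole-number counts per gene and FPKM for each sample, per the file headers. The deposited counts were used as they stand. The FPKM values were made by the authors from each gene's length and the sample's own count total: the length that counts, totals and FPKM imply was the same in every sample to within 2.98e-14 of its value. The submitters' processing notes name Trim Galore 0.6.4, Bowtie2 2.4.2, HISAT2 2.2.0, HTSeq 0.13.5 and edgeR, without a version for the last, and the builds GRCh38, GRCm39 and Rnor_6.0. Neither the labels nor the notes state the strand setting of the counting, multi-mapping rules or filters. Reads shared between paralogs or overlapping genes could have been split or dropped, so such genes are uncertain. The table held 22831 genes, 174 of them without a symbol, and 0 genes of the mitochondrial chromosome. Every per-sample column was mapped to a sample.

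Strand relations between genes came from GENCODE M21, an annotation of GRCm38. It was joined to the table by gene ID for 22506 of 22831 genes and used only for which genes lie opposite each other. Positions in the text are the table's own. A protein-coding gene counted as having no opposite-strand gene when no annotated gene on the other strand covered any of its exons (9510 genes). A noncoding gene (lncRNA or TEC) counted as opposite a protein-coding gene when their exons overlapped by at least 100 bp (1711 genes). Pairs were compared by counts per kb of exon where they had at least 100 counts together, with a percentile bootstrap interval at 95% from 2000 draws. On simulated data counted on the annotated strand the median log2 ratio was -3.98, and counted on the opposite strand 4.00. The size of the ratio was set in the simulation, so these values test only that the measure returns it. They give no size to compare with the real ratio. Group means of the sense-to-opposite ratio and the count totals were compared by two-sided exact permutation tests, which cannot go below 0.1 with 3 against 3.

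Counts were tested with edgeR 4.0.16 (TMM factors, filterByExpr with its minimum count of 10 and minimum total of 15, glmQLFit and glmQLFTest) in 1 fit of all 9 samples with group as the sole factor, two-sided, with Benjamini-Hochberg adjustment over the genes of a contrast and a call at an adjusted p under 0.05. The filter left 12548 genes. A design for FPKM had been written before the data were examined, together with this one for a table that holds counts. Since the table holds counts, the count design is the one reported and limma 3.58.1 on log2(FPKM + 1) is an alternative. The contrasts were palmitic acid against control, palmitic acid + carnitine against palmitic acid, and palmitic acid + carnitine against control. These p-values cover the spread between the libraries of this series.

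Gene lists (32, with 864 symbols, 807 of them matched to the table and 14 of those through a synonym) were fixed from textbook knowledge before the data were examined and tested with limma's camera at a preset correlation of 0.01, adjusted over the lists of a contrast. Lists with fewer than 5 tested members were left out: mitochondrially encoded genes, which the table lacks, and adipocyte markers. Camera was also run with an estimated correlation. Counts adjusted over the list alone use the members' edgeR p-values with the adjustment restricted to the list.

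Genes were named by a rule fixed before the data were examined. It takes up to 12 higher and 12 lower genes per contrast past the threshold with groups that do not overlap and a mean FPKM of at least 5 in the higher group, leaving out predicted genes, clone names and pseudogenes, or the 5 with the smallest p where none passes. It also takes up to 4 members of each list, the 12 genes most moved back by carnitine, and 40 genes named in advance. Of these 40, 30 were tested, and 9 of the 30 have an opposite-strand gene over an exon. Cpt1b, Ucp3, Acot1, Cd36, Slc22a5, Slc2a4, Ppargc1a and Il6 had too few counts, and Mstn is not in the table. Not every gene of the rule is named in the text. Genes named outside the rule are given as chosen after their values were seen.

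The edgeR and camera steps were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 genes changed. For palmitic acid against control, genes changed by a log2 of 0.5, 1 and 2 were recovered at 0%, 3.03% and 65.2% among all 12548 genes, and at 6.06%, 31.3% and 67.2% among 5920 genes with no opposite-strand gene. For palmitic acid + carnitine against palmitic acid the shares were 0%, 6.06% and 63.6%, and 6.06%, 35.8% and 73.1%. A change of a log2 of 1 in a single gene was thus mostly below what all-gene testing could detect. The simulation kept both the depth of 2.31 to 5.14 M counts and the spread between these libraries, so it does not separate these limits. A shifted list was recovered in each comparison, with 0 other lists called. Genes were drawn independently there, so this does not show how often lists are called falsely when genes move together.

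Alternatives fixed before the data were examined were RLE factors, no filter, DESeq2 1.42.0, the 6 samples of the groups compared, the replicate number as a block, each replicate left out in turn, limma on FPKM with pseudocounts of 0.1 and 5, other FPKM filters and scalings, no trend, a minimum log2 fold change of 1, and camera with an estimated correlation or ranks. Limma on log2(FPKM + 1) had been written in advance as the design for a table without counts. Its use as an alternative was not fixed in advance. Those chosen after seeing the data were fits of genes with no opposite-strand gene, the library's log2 sense-to-opposite ratio as a covariate, noncoding opposite genes alone, and leaving out palmitic acid replicate 1 and control replicate 3, whose ratios lay apart from their groups. Replicates were separate libraries and not copies: the chi-square per degree of freedom between replicates was 3.65 to 52.3. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9, R 4.3.3 and bedtools 2.31.1 were used.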

Results

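Gene expression was measured by stranded mRNA sequencing in C2C12 myotubes, the multinucleated muscle fibers that this mouse myoblast line forms in low serum. The series asks what carnitine does in myotubes given palmitic acid, a saturated fatty acid. Each of 3 groups held 3 libraries: untreated control, 200 µM palmitic acid, and 200 µM palmitic acid with 1000 µM carnitine, the carrier that takes long-chain fatty acids into mitochondria. The labels give the duration as 48 with a garbled unit, so the unit is not stated here. The deposited table held raw counts for 22831 mouse genes. Total counts were 2.31, 2.73 and 3.31 M in control replicates 1, 2 and 3. They were 5.14, 3.44 and 3.33 M in palmitic acid replicates 1, 2 and 3, and 3.09, 2.45 and 2.63 M in palmitic acid + carnitine replicates 1, 2 and 3. Below, CPM (counts per M counts, TMM-scaled) are means ± SD with n = 3 libraries per group, log2 fold changes are given ± SE, and positions are GRCm39 as deposited.

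Many genes, muscle genes among them, carried fewer counts than the genes annotated on the other strand of the same DNA, though not all did. Ckm, the muscle creatine kinase (chromosome 7, 19138701 to 19156766), had 6096 counts over the 9 libraries, against 58724 for A930016O22Rik, a noncoding gene on the other strand (chromosome 7, 19151391 to 19155342). Tnnc2, the fast-muscle troponin C (chromosome 2, 164619081 to 164621887), had 6306 counts, against 150442 for Ube2c, a cell cycle gene opposite it (chromosome 2, 164611818 to 164620742). Among genes outside the sarcomere list, Gnas, the stimulatory G protein subunit (chromosome 2, 174126113 to 174188537), had 29647 counts, against 732803 for Gm20721 (Nespas lies there too) on the other strand (chromosome 2, 174172112 to 174188505). The intermediate filament gene Des (111145 against 224 for Gm15179), Ttn (27637 against 3491 for Gm13938), Myh2 (1900 against 35 for 9430073C21Rik) and Mybpc1 (70 against 50 for Gm48752) went the other way. These genes were chosen after their values were seen. Among 1385 pairs of a noncoding gene and the protein-coding gene whose exons it lies opposite, 87.7% had more counts per kb on the noncoding gene, with a median log2 ratio of 3.78 (95% bootstrap interval 3.62 to 3.91). Counts of a gene with such a partner therefore cannot be assigned to that gene alone, and such partners are named where the gene is first given. Genes without a partner are not thereby safe. If reads were counted on the wrong strand, their counts would be residual reads of the other orientation. Every rise or fall below is a change in the counts as deposited.

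Libraries differed in how their counts were divided between strands. The sense-to-opposite ratio is the count total of protein-coding genes with no annotated gene on the other strand of their exons, divided by the count total of noncoding genes opposite a protein-coding gene. It was 0.685, 0.633 and 1.18 in control replicates 1, 2 and 3, 3.48, 1.21 and 1.22 in palmitic acid replicates 1, 2 and 3, and 0.831, 0.653 and 0.701 in palmitic acid + carnitine replicates 1, 2 and 3. Its mean over 3 libraries was 1.97 with palmitic acid, 0.832 in control and 0.729 with carnitine. By a two-sided exact permutation test p was 0.1 for palmitic acid against each other group, the smallest that 3 against 3 allows, and 0.9 for palmitic acid + carnitine against control. Total counts differed in the same order, with means of 3.97, 2.78 and 2.72 M in palmitic acid, control and palmitic acid + carnitine (exact permutation p = 0.1, 0.1 and 0.9 for the same comparisons). The first principal component of the log2 counts held 48.4% of the variance. It followed the sense-to-opposite ratio across the 9 libraries (Spearman rho = 0.967). Across all genes tested, protein-coding genes with no opposite-strand gene had a median log2 fold change of 0.27 with palmitic acid against control and -0.34 with carnitine against palmitic acid, and noncoding genes opposite protein-coding ones had -0.80 and 0.90.

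**Figure D1:**
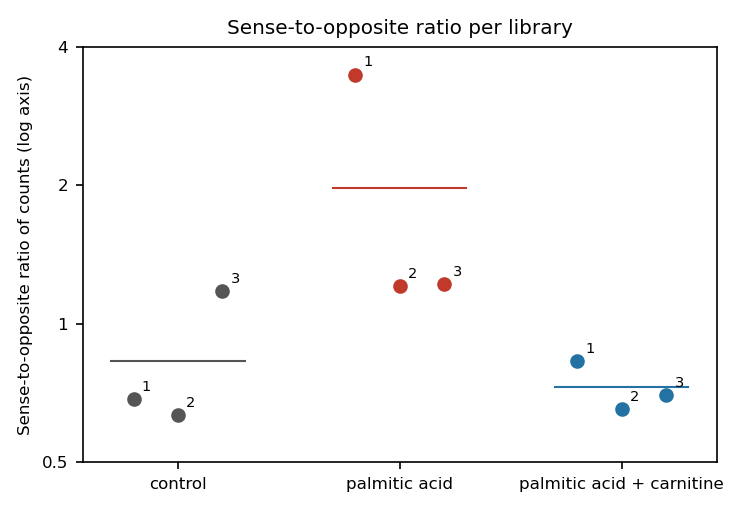
Sense-to-opposite ratio of counts (vertical log axis, no unit) for each of the 9 libraries, labelled by replicate, with the group mean as a line. Palmitic acid replicate 1 sits at 3.48, and control replicate 3, at 1.18, lies next to palmitic acid replicates 2 and 3 at 1.21 and 1.22.

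Palmitic acid against control asked how the myotubes respond to the fatty acid. PPAR target genes, which lipid-sensing nuclear receptors switch on, rose as a group, with a median log2 fold change of 0.53 over 17 members tested, 13 of them above 0 (camera, adjusted p = 0.00134; adjusted p = 0.397 with an estimated correlation, given below as estimated). Over all genes tested none of them passed, and adjusted over the list alone 5 rose. In the same fit all genes with no opposite-strand gene had a median of 0.27. The folds of Angptl4, Cpt1a, Plin2 and Acaa2 below are to be read beside it. Angptl4, a secreted inhibitor of lipoprotein lipase, went from 29.9 ± 13.0 to 93.3 ± 17.6 CPM (log2 fold change 1.63 ± 0.31). Cpt1a, which makes the acylcarnitines that enter mitochondria, went from 18.0 ± 6.11 to 41.5 ± 7.89 (1.19 ± 0.39), Plin2, a lipid droplet coat protein, from 52.4 ± 16.3 to 90.7 ± 3.29 (0.78 ± 0.27), and Acaa2, the last enzyme of mitochondrial beta-oxidation, by 0.97 ± 0.28. Ucp2, a mitochondrial carrier protein whose exons lie opposite Dnajb13, was the other one, at 1.76 ± 0.34.

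**Figure D2:**
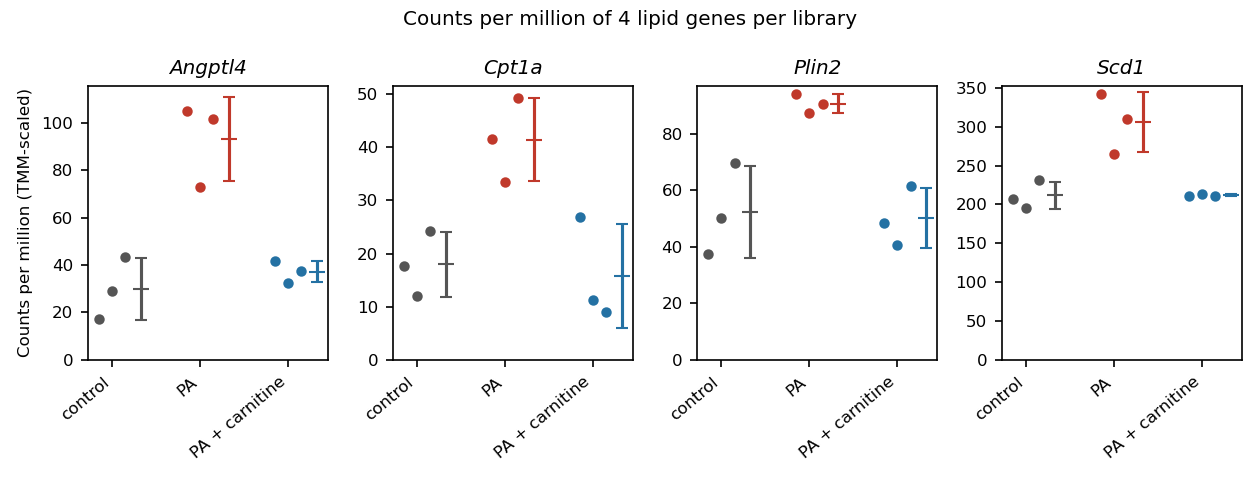
CPM (vertical axis, TMM-scaled) of Angptl4, Cpt1a, Plin2 and Scd1 in each library, with the mean and SD of 3 libraries beside the points. Angptl4 averaged 93.3 with palmitic acid (PA), 29.9 in control and 37.2 with palmitic acid and carnitine. In the same fit genes with no opposite-strand gene had a median log2 fold change of 0.27 with PA against control. It was -0.34 with carnitine against PA.

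Other lipid groups were higher with palmitic acid as well, beside the 0.27 median of genes with no opposite-strand gene. Carnitine transport and acyltransfer genes rose with a median of 0.61, adjusted p = 0.0322, estimated 0.397. Mitochondrial beta-oxidation genes rose (0.50, adjusted p = 0.0118, estimated 0.397), with 14 of 18 above 0, among them Acads at 0.66 ± 0.23 and Acadl at 0.54 ± 0.23, values that did not pass. Fatty acid synthesis and desaturation genes rose (0.47, adjusted p = 0.0102, estimated 0.397), 16 of 17 above 0, as did triglyceride synthesis and storage genes (0.37, adjusted p = 0.0118, estimated 0.397) and cholesterol synthesis genes (0.48, adjusted p = 0.0167, estimated 0.397). Scd1, a stearoyl-CoA desaturase, had 211 ± 17.9 CPM in control and 306 ± 38.9 with palmitic acid, and Scd2 differed by 0.49 ± 0.27; neither passed. Among genes with no opposite-strand gene none of these 5 lists passed (adjusted p = 0.190 for beta-oxidation to 0.400 for carnitine and cholesterol genes). Peroxisomal oxidation genes (0.29, adjusted p = 0.252) and sphingolipid genes (-0.11, adjusted p = 0.903) did not pass.

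Mitochondrial and housekeeping groups were higher too, beside the same 0.27 median. Oxidative phosphorylation subunits rose (0.37, adjusted p = 0.000208, estimated 0.397), with 63 of 77 above 0, along with tricarboxylic acid cycle genes (0.36, adjusted p = 0.00976, estimated 0.425), ribosomal proteins (0.36, adjusted p = 0.000408, estimated 0.425), glycolysis genes (0.37, adjusted p = 0.0292, estimated 0.425) and branched-chain amino acid breakdown (0.39, adjusted p = 0.0467, estimated 0.397). Adjusted over the list alone Rpl34 rose (1.07 ± 0.26), Mtor, the growth-controlling kinase of the insulin signalling list, rose (1.11 ± 0.28), and the glycolytic kinase gene Pfkp, opposite Pitrm1, fell (-1.34 ± 0.33). Insulin signalling genes rose with a median of 0.24, adjusted p = 0.0167, estimated 0.397, whereas Irs1 (opposite Gm9747) and Irs2 (opposite 9530052E02Rik), the insulin receptor substrates, stood at 0.14 ± 0.22 and 0.28 ± 0.50. Among genes with no opposite-strand gene none of these 6 lists passed, with oxidative phosphorylation at 0.06, adjusted p = 0.307 and the tricarboxylic acid cycle at 0.15, adjusted p = 0.468. Mitochondrial biogenesis genes did not pass (-0.04, adjusted p = 0.854), and adjusted over the list alone Tfb1m, opposite Tiam2, fell (-1.52 ± 0.39).

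Stress, muscle and cell-type groups were mixed. ATF4 targets of the integrated stress response rose (0.35, adjusted p = 0.0467, estimated 0.397), although Atf4 itself differed by 0.39 ± 0.26 and Trib3, Fgf21 and Gdf15 by -0.22 ± 0.75, 0.65 ± 0.77 and -0.17 ± 0.71; Chac1 stood at 1.07 ± 0.46 and Ddit3, opposite Gm4189 and Mars, at -0.84 ± 0.31, and none of the 6 passed. NRF2 and antioxidant genes rose (0.21, adjusted p = 0.0467, estimated 0.438), with Hmox1 at 0.20 ± 0.28 and Txnip, opposite Gm15441, at 0.27 ± 0.24. Atrophy genes rose (0.30, adjusted p = 0.0260, estimated 0.425), while the muscle ubiquitin ligases Fbxo32 (opposite Gm15943) and Trim63 stood at 0.40 ± 0.31 and -0.68 ± 0.64. Fibroblast and matrix markers rose (0.46, adjusted p = 0.000208, estimated 0.397), with Tnc, opposite 8030451A03Rik, higher over the list alone (1.03 ± 0.25). None of these 4 lists passed among genes with no opposite-strand gene, where antioxidant genes had -0.06, adjusted p = 0.835, ATF4 targets 0.09, adjusted p = 0.710, atrophy genes 0.07, adjusted p = 0.400 and matrix markers 0.18, adjusted p = 0.196. Unfolded protein response genes did not pass (0.20, adjusted p = 0.0605), with the chaperone Hspa5 at 0.18 ± 0.24, nor did sarcomere genes (0.21, adjusted p = 0.0676), with Acta1 (opposite Gm20388), Ckm, Myh3 and Myh4 at 0.66 ± 0.31, 0.32 ± 0.26, 0.20 ± 0.28 and -0.41 ± 0.27. Myogenic regulators (0.35, adjusted p = 0.0605; Myog 0.26 ± 0.24 and Myod1 0.33 ± 0.27), reserve cell markers (0.35, adjusted p = 0.0676), inflammatory cytokine genes (0.53, adjusted p = 0.0682; Ccl2, opposite Gm17268, 0.65 ± 0.73) and osteoblast markers (0.55, adjusted p = 0.0682) did not pass. Nor did autophagy and lysosome genes (0.25, adjusted p = 0.0851), apoptosis genes (0.25, adjusted p = 0.218), heat shock genes (0.08, adjusted p = 0.447), interferon-stimulated genes (-0.52, adjusted p = 0.571) or cell cycle markers (0.10, adjusted p = 0.383). The test placed sphingolipid and mitochondrial biogenesis genes on the higher side, against the sign of their medians. Among the cell cycle markers, Ccna2, Kif20a and Ccne2, opposite Exosc9, Cdc23 and Ints8, fell over the list alone (-1.27 ± 0.37, -1.37 ± 0.38 and -2.09 ± 0.61).

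In all, 16 of 30 lists rose with palmitic acid and 0 fell, and with an estimated correlation 0 passed (smallest adjusted p = 0.397). Camera compares a list with the other genes tested, and those included 1289 noncoding opposite genes at a median of -0.80. This background alone could push lists of protein-coding genes to the higher side. With the library's ratio as a covariate across all genes 1 list rose and 0 fell, though the ratio also differed between the groups. No single gene of 12548 passed in edgeR's quasi-likelihood test, where the smallest adjusted p was 0.139. At an unadjusted p under 0.05 there were 2453 genes, 712 higher and 1741 lower, beside 627 that chance would give. DESeq2 called 474 genes, 35 higher and 439 lower, and limma on log2(FPKM + 1) called 3. Without control replicate 3, edgeR called 768 genes (173 higher and 595 lower), and without both that library and palmitic acid replicate 1 it called 2369 (763 higher and 1606 lower). The 5 genes with the smallest p, none past the threshold, were Tubb3, a neuronal tubulin (1.92 ± 0.33), Gm6566, opposite Gstz1 (-2.34 ± 0.44), Gnpnat1, opposite Styx (-3.04 ± 0.56), Ctbs, opposite Spata1 (-2.53 ± 0.48), and Ucp2.

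Restricting the test to genes with no opposite-strand gene, a step chosen after seeing the data, left the PPAR targets as the 1 list of 29 that passed. All 10 tested there were higher with palmitic acid (median 0.43, adjusted p = 0.000298; adjusted p = 0.224 with an estimated correlation). Among these 5920 genes edgeR called 65, 4 higher and 61 lower. The 4 higher ones were Angptl4 (1.36 ± 0.23, adjusted p = 0.00559), Tubb3 (1.65 ± 0.35, adjusted p = 0.0163), Plppr2, a membrane lipid phosphatase-related protein (2.07 ± 0.45, adjusted p = 0.0190), and Snai1, a repressor of epithelial genes (1.19 ± 0.30, adjusted p = 0.0444). Lower ones included Atg7, an enzyme of autophagosome formation (-1.87 ± 0.30), the spliceosomal peptidyl-prolyl isomerase Ppig (-1.61 ± 0.27), and Sqle and Acat2 of cholesterol synthesis (-1.16 ± 0.27 and -1.03 ± 0.26), chosen after their values were seen. All 61 lower genes were also lower in control replicate 3 than in the mean of the other controls. Adjusted over the list alone, Angptl4, Cpt1a, Plin2 and Acaa2 rose, and in the sarcomere list Myh4, Tnnt1, Tnnt2 and Tpm1 fell (-0.69 ± 0.21 for Myh4). With the library's ratio as a covariate 1 gene was called, the embryonic myosin Myh3, at 0.33 ± 0.07, and none of the 65 remained: Atg7 and Ppig came to -0.64 ± 0.22 and -0.58 ± 0.24, whereas Angptl4 and Tubb3 stood at 1.17 ± 0.27 and 1.62 ± 0.49, close to their values without it but with a larger SE. Without palmitic acid replicate 1 there were 23 calls, 22 of them among the 65, and without control replicate 3 there were 192, all 65 included.

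**Figure D3:**
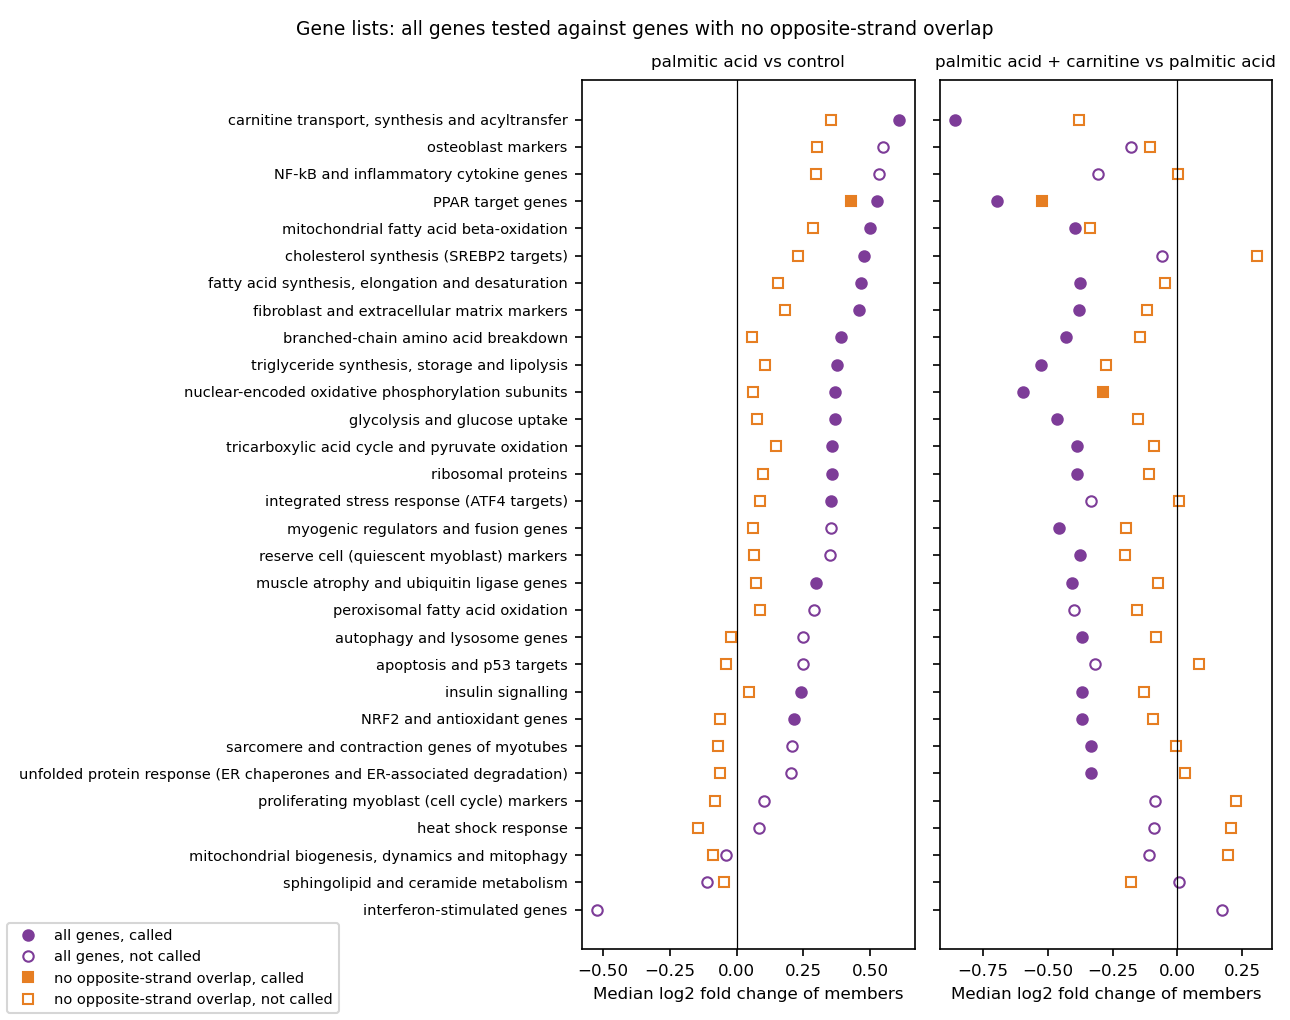
Median log2 fold change of the members of each gene list (horizontal axis) with all genes tested (circles) and among genes with no opposite-strand gene (squares), for palmitic acid against control (left) and palmitic acid + carnitine against palmitic acid (right); filled symbols passed the camera test. PPAR target genes are filled in both panels under both tests, with medians of 0.53 and 0.43 on the left and -0.70 and -0.52 on the right.

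Palmitic acid + carnitine against palmitic acid asked what carnitine changes in fatty acid-treated myotubes. PPAR target genes fell as a group, with a median log2 fold change of -0.70 and 14 of 17 members below 0 (adjusted p = 0.00464; adjusted p = 0.378 with an estimated correlation). Angptl4 had 37.2 ± 4.59 CPM with carnitine (-1.32 ± 0.31), Cpt1a 15.7 ± 9.77 (-1.38 ± 0.39), Plin2 50.2 ± 10.6 (-0.85 ± 0.27), Acaa2 19.1 ± 5.16 (-1.14 ± 0.28) and Ucp2 16.1 ± 3.65 (-1.03 ± 0.32). Over all genes tested none of the 5 passed, and all 5 fell when adjusted over the list alone. All genes with no opposite-strand gene had a median of -0.34 in the same fit. Pdk4, which restrains glucose oxidation and is also a PPAR target, stood at 0.53 ± 0.35 with palmitic acid and -0.38 ± 0.35 with carnitine, and passed neither test.

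Fuel-burning groups fell with carnitine, beside a median of -0.34 for genes with no opposite-strand gene. Oxidative phosphorylation subunits fell, 69 of 77 below 0 (-0.60, adjusted p = 1.05e-07, estimated 0.402), and over the list alone Atp5g1, Uqcrfs1 and Cox7c fell (-1.35 ± 0.28, -1.09 ± 0.26 and -1.14 ± 0.29). Carnitine transport and acyltransfer genes fell (-0.86, adjusted p = 0.00592, estimated 0.352), with Cpt1a and Cpt1c, its brain-type relative opposite 6530437J22Rik (-1.94 ± 0.58), lower over the list alone, and with the carnitine-acylcarnitine carrier Slc25a20 at -0.86 ± 0.39 and Crat, opposite Dolpp1 and Gm16323, at -0.50 ± 0.30. Beta-oxidation genes fell (-0.39, adjusted p = 0.00974, estimated 0.352; Cpt1a, Acaa2 and Acads over the list alone), as did tricarboxylic acid cycle genes (-0.39, adjusted p = 0.000643, estimated 0.402), triglyceride genes (-0.53, adjusted p = 0.00592, estimated 0.402), fatty acid synthesis genes (-0.38, adjusted p = 0.0437, estimated 0.457; Scd1 -0.53 ± 0.23 and Scd2 -0.48 ± 0.27) and glycolysis genes (-0.46, adjusted p = 0.0142, estimated 0.437), among which Pfkp rose over the list alone (1.29 ± 0.33). Ribosomal proteins fell (-0.39, adjusted p = 2.53e-05, estimated 0.402), and so did branched-chain amino acid breakdown (-0.43, adjusted p just under the threshold, estimated 0.402), insulin signalling (-0.37, adjusted p = 0.0311, estimated 0.402; Irs1 -0.22 ± 0.22, Irs2 -0.08 ± 0.50), NRF2 and antioxidant genes (-0.37, adjusted p = 0.00592, estimated 0.402) and unfolded protein response genes (-0.33, adjusted p = 0.0110, estimated 0.352). Gpx1, Sod2, Srxn1 and Osgin1 fell over the antioxidant list alone, with Gpx1 at -1.21 ± 0.32, and the stress sensor Ern1 over the unfolded protein response list alone (-1.43 ± 0.35). Of these 12 lists only oxidative phosphorylation passed among genes with no opposite-strand gene, where the others ran from an adjusted p of 0.0870 for ribosomal proteins to 0.905 for the unfolded protein response (median 0.03).

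Muscle groups were lower with carnitine when all genes were tested. Sarcomere genes (-0.33, adjusted p = 0.00592, estimated 0.402; Acta1 -0.61 ± 0.31, Ckm -0.55 ± 0.26, Myh3 -0.10 ± 0.28, Myh4 0.15 ± 0.27), myogenic regulators (-0.46, adjusted p = 0.00592, estimated 0.352; Myog -0.57 ± 0.24, Myod1 -0.31 ± 0.27) and atrophy genes (-0.41, adjusted p = 0.00592, estimated 0.402; Fbxo32 -0.46 ± 0.31, Trim63 -0.43 ± 0.68) fell. The fusion gene Mymk (-0.91 ± 0.27) and the muscle methyltransferase gene Smyd1 (-1.32 ± 0.29) fell over the myogenic list alone. Fibroblast and matrix markers (-0.38, adjusted p = 0.00592, estimated 0.476), reserve cell markers (-0.38, adjusted p = 0.0275, estimated 0.352) and autophagy and lysosome genes (-0.37, adjusted p = 0.0142, estimated 0.402) fell, with Notch3, opposite Gm17276, lower over the reserve cell list alone (-1.14 ± 0.31). None of these 6 lists passed among genes with no opposite-strand gene, where sarcomere genes had -0.01, adjusted p = 0.979, myogenic regulators -0.20, adjusted p = 0.113 and atrophy genes -0.08, adjusted p = 0.341. ATF4 targets (-0.33, adjusted p = 0.174; Atf4 -0.29 ± 0.26, Ddit3 0.73 ± 0.31, Chac1 -0.39 ± 0.45, Trib3 -0.88 ± 0.80, Fgf21 -0.12 ± 0.75, Gdf15 -0.64 ± 0.74), cholesterol synthesis (-0.06, adjusted p = 0.548) and inflammatory genes (-0.31, adjusted p = 0.117; Ccl2 -0.59 ± 0.73) did not pass. The other lists that did not pass were peroxisomal oxidation (-0.40, adjusted p = 0.235), sphingolipid (0.01, adjusted p = 0.954), interferon (0.17, adjusted p = 0.610), mitochondrial biogenesis (-0.11, adjusted p = 0.673), apoptosis (-0.32, adjusted p = 0.147), heat shock (-0.09, adjusted p = 0.758), cell cycle (-0.09, adjusted p = 0.773) and osteoblast genes (-0.18, adjusted p = 0.421). Cell cycle genes lay on the higher side by the test and sphingolipid genes on the lower, against the sign of their medians. Hspa5, Hmox1 and Txnip stood at -0.20 ± 0.24, -0.61 ± 0.28 and -0.43 ± 0.25.

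Of 30 lists 19 fell and 0 rose with carnitine, and with an estimated correlation 0 passed (smallest adjusted p = 0.352). The noncoding opposite genes in camera's background had a median of 0.90 here, which could push lists of protein-coding genes to the lower side. With the library's ratio as a covariate across all genes 1 list fell and 1 rose. edgeR called 0 of 12548 genes (smallest adjusted p = 0.125), with 3046 at an unadjusted p under 0.05, 1999 higher and 1047 lower, beside 627 by chance. DESeq2 called 873, 751 higher and 122 lower, and limma called 6. Without control replicate 3 edgeR called 6, and without both that library and palmitic acid replicate 1 it called 1685 (1361 higher and 324 lower). The 5 genes with the smallest p were Ctbs (2.64 ± 0.48), 2610316D01Rik (2.25 ± 0.43), Gm6566 (2.28 ± 0.44), Zfp974, opposite Gm26891 (2.39 ± 0.46), and Gnpda2, opposite Guf1 (3.47 ± 0.68), and none passed.

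Among genes with no opposite-strand gene edgeR called 66 with carnitine, 60 higher and 6 lower. Angptl4 was among the 6 lower ones (-0.99 ± 0.22, adjusted p = 0.0275), with Tmem109 (-0.95 ± 0.22), Ndrg4 (-0.66 ± 0.16), the slow-muscle troponin Tnni1 (-0.54 ± 0.14), the autophagy gene Atg101 (-1.40 ± 0.36) and Igdcc4 (-1.75 ± 0.45). Higher ones included Ppig (1.86 ± 0.27), Atg7 (1.56 ± 0.30) and the cystine transporter Slc7a11 (0.87 ± 0.22), chosen after their values were seen. PPAR targets (-0.52, adjusted p = 0.000608; adjusted p = 0.339 with an estimated correlation) and oxidative phosphorylation subunits (-0.29, adjusted p = 0.000608; adjusted p = 0.557 with an estimated correlation) were the 2 lists that fell there. With the library's ratio as a covariate 0 genes were called, and 162 had an unadjusted p under 0.05, beside 296 by chance. Without palmitic acid replicate 1 there were 25 calls, all among the 66, and Angptl4 was not one of them (log2 fold change -0.96 ± 0.25, adjusted p = 0.0723); without control replicate 3 there were 112.

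Genes that palmitic acid changed and carnitine moved back were 0 of 12548 in edgeR, 382 in DESeq2 and 2 in limma, and 35 among the 5920 genes with no opposite-strand gene. The 35 were Angptl4 and 34 of the 61 lower genes, Atg7 and Ppig among them. Independent lists of these sizes would share 0.618 lower genes and 0.00405 higher ones, and simulated unchanged groups with the same shared palmitic acid libraries gave a mean of 0.02. The figures for independent lists ignore the shared libraries. The simulations, also used for the correlations below, drew each gene independently. They held no shift shared by a whole library, such as one in the ratio. How many genes that would move back was not simulated. The log2 fold changes of both comparisons correlated at -0.63 across these genes, beside a simulated mean of -0.45, with a covariance of -0.22 against -0.09; across all genes tested the correlation was -0.82 against -0.47 and the covariance -0.53 against -0.12. Genes are not independent replicates, and the 3 shared libraries cannot be split into parts of 2, so part of the excess may come from them.

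Palmitic acid + carnitine against control asked how far the double-treated myotubes differ from untreated ones. Cholesterol synthesis genes rose, with 19 of 26 above 0 (median 0.22, adjusted p = 0.0107), and oxidative phosphorylation subunits fell, with 55 of 77 below 0 (median -0.15, adjusted p = 0.0107). With an estimated correlation neither passed (adjusted p = 0.943 for each). The cholesterol synthesis call was also lost in limma on log2(FPKM + 1) and without each of control replicate 1, control replicate 2 and palmitic acid + carnitine replicate 1, and the oxidative phosphorylation call without each of control replicate 3 and palmitic acid + carnitine replicates 1 and 2. PPAR targets had a median of -0.10, adjusted p = 0.918, with Angptl4 at 0.30 ± 0.32, Cpt1a at -0.18 ± 0.41, Plin2 at -0.07 ± 0.27 and Ucp2 at 0.73 ± 0.35.

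The other 27 lists did not pass. Their largest medians in size were those of osteoblast markers (0.19, adjusted p = 0.248), reserve cell markers (-0.19, adjusted p = 0.533) and carnitine transport and acyltransfer genes (-0.18, adjusted p = 0.248). Beta-oxidation (-0.04, adjusted p = 0.918), fatty acid synthesis (0.02, adjusted p = 0.422), sarcomere (-0.12, adjusted p = 0.114) and ATF4 target genes (0.08, adjusted p = 0.476) lay near 0. For PPAR targets, insulin signalling and interferon genes the test pointed higher against a negative median, and for branched-chain genes lower against a positive one. edgeR called 0 of 12548 genes, with 346 at an unadjusted p under 0.05, fewer than the 627 by chance. DESeq2 called 0 and limma 3. The 5 smallest p values belonged to Rbsn, an endosome fusion protein (-1.81 ± 0.37), the activin receptor Acvr1b (-4.22 ± 0.98), the nicotinamide riboside kinase Nmrk2, opposite Atcayos (-1.46 ± 0.36), Wdr43, opposite CT010429.2 (-1.47 ± 0.37), and Sap30 (-1.14 ± 0.29), all with an adjusted p of 1. Among genes with no opposite-strand gene 0 genes and 0 lists passed, and cholesterol synthesis, oxidative phosphorylation and cell cycle lists each had an adjusted p of 0.0516. Adding the library's ratio as a covariate there called 2 genes, Col3a1, a fibrillar collagen, higher and Ndrg4 lower.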

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

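Single-gene calls depended on the setting. The fit reported called 0 genes, so no gene could lose a call or reverse. Of 3549 values for 129 gene results under 31 alternatives, 3460 stayed uncalled, 89 passed and 222 uncalled ones changed sign. Of 2664 values for 90 list results, 2255 were the same, 250 lost and 128 gained a call and 31 reversed. Below, 3 counts in a series stand for palmitic acid against control, palmitic acid + carnitine against palmitic acid, and palmitic acid + carnitine against control, and the cause was not tested where a value moved or reversed.

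Genes called were 0, 0 and 0 with RLE factors, with the 6 samples of the groups compared, with noncoding opposite genes alone (which hold no lists) and with a minimum log2 fold change of 1. Without the filter they were 1118, 1366 and 5, with 895 moved back by carnitine, and with DESeq2 474, 873 and 0, with 382 moved back and 4 lists for the last contrast. With limma they were 4, 5 and 2 (pseudocount 0.1; 3 moved back, 1 list for the last contrast), 4, 7 and 2 (pseudocount 5; 2 moved back), 5, 4 and 3 (no filter; 3 moved back, 26 lists for the first contrast), 2, 3 and 0 (stricter filter; 1 moved back), 5, 7 and 3 (TPM; 3 moved back, 1 list for the last contrast), 7, 5 and 3 (median-ratio scaling; 2 moved back), 4, 7 and 3 (quantile normalization; 3 moved back), 6, 7 and 4 (no trend; 3 moved back, 1 list for the last contrast) and 3, 6 and 3 (pseudocount 1; 2 moved back, 1 list for the last contrast). Camera with an estimated correlation called 0, 0 and 0 lists, and with ranks 17, 18 and 2.

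With the replicate block edgeR called 0, 0 and 0 genes and 16, 19 and 2 lists, with 2356, 2876 and 263 genes at an unadjusted p under 0.05. The replicate numbers share only a number: of 9 same-number pairs 4 deviated together at a correlation over 0.1 (range -0.394 to 0.262), and 1 of 9 libraries correlated best with its own number. The block changed no count of calls.

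Leaving out each replicate in turn gave 0 to 768 genes for the first contrast, 0 to 6 for the next and 0 to 0 for the last, with 0 to 6 moved back; every count above 0 came without control replicate 3. Lists ranged from 11 to 20, 16 to 19 and 0 to 3. Without both palmitic acid replicate 1 and control replicate 3 there were 2369, 1685 and 9 genes, 1401 moved back, and 10, 16 and 2 lists.

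Genes with no opposite-strand gene gave 65, 66 and 0 calls, 35 moved back, and 1, 2 and 0 lists. With the library ratio as a covariate there were 1, 0 and 2 genes and 1, 2 and 0 lists in that set, and 1 and 2 lists for the first contrasts across all genes. Without palmitic acid replicate 1 the set gave 23, 25 and 0 genes, 13 moved back, and 1, 1 and 0 lists; without control replicate 3, 192, 112 and 0 genes, 88 moved back, and 1, 2 and 0 lists; without both, 149, 69 and 7 genes, 55 moved back, and 1, 1 and 0 lists.

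PPAR targets kept their call in both palmitic acid contrasts under every alternative with a value per list except the covariate across all genes (adjusted p = 0.123 and 0.261). They lost it with an estimated correlation, and with ranks only the number of lists was kept. Lists that reversed did so among genes with no opposite-strand gene or with the covariate. With palmitic acid the adjusted p of antioxidant genes became 0.835 in that set, 0.341 there with the covariate, 0.603 with the covariate across all genes, and 0.773 and 0.923 without palmitic acid replicate 1 and without both libraries. That of oxidative phosphorylation became 0.348 and 0.712 with the covariate (set and all genes) and 0.985 without palmitic acid replicate 1, tricarboxylic acid cycle 0.703 and 0.890, glycolysis 0.703 with the covariate and 0.985 without palmitic acid replicate 1, atrophy genes 0.888 and 0.890, ribosomal proteins 0.703 and 0.945, and cholesterol synthesis 0.890. With carnitine sarcomere genes came to 0.979 in the set. With the covariate there, fatty acid synthesis came to 0.633, antioxidant genes and insulin signalling to 0.973 each, and tricarboxylic acid cycle, glycolysis and reserve cell markers to 0.964 each. With the covariate across all genes, cholesterol synthesis was called higher (0.00314), and fatty acid synthesis came to 0.847 and antioxidant genes and insulin signalling to 0.933 each. Fatty acid synthesis came to 0.930 without palmitic acid replicate 1 and 0.993 without both libraries, as did autophagy genes (0.993).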

Other observations

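Some cell cycle and muscle genes with no opposite-strand gene gave values not described above. Cell cycle markers in palmitic acid + carnitine against control had 22 of 25 members above 0 (median 0.30, adjusted p = 0.0516), a list that did not pass. Mymk, needed for myoblast fusion, rose with palmitic acid over the myogenic list alone (0.54 ± 0.17) and fell with carnitine (-0.56 ± 0.17). In the matrix list Col6a3 rose with palmitic acid over the list alone (0.49 ± 0.15), and in the glycolysis list Pgam2 and Slc16a3 rose with carnitine (0.70 ± 0.24 and 0.81 ± 0.27).

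The tests in the next 3 paragraphs were chosen after the results they concern were seen, and the counts of other groupings before those counts were made. The high counts on genes opposite abundant muscle genes argue against genomic DNA as the main source of reads. That would put the median log2 ratio of counts per kb near 0, and it was 3.78, with an interval of 3.62 to 3.91. A smaller share of genomic DNA would only lower the ratio and is not excluded. By library the median ran from 2.24 in palmitic acid replicate 1 to 4.64 in control replicate 2. What also stays open is that reads of this stranded kit were counted on the strand opposite to the transcripts: 87.7% of pairs (95% exact interval 85.8% to 89.3%) had more counts per kb on the noncoding gene. That share restates the pattern, and transcription of both strands could give it too, so it decides nothing. Noncoding counts were higher where an exon on the other strand overlapped. LncRNA genes with at least 100 bp of such overlap had a median of 502 counts over the 9 libraries, against 7 without it. For TEC genes these medians were 638.5 and 5. To give this pattern, transcription of the noncoding strand would have to exceed that of the coding strand in most pairs. That was not tested, nor was any other biological explanation. If reads were counted on the wrong strand, the counts of genes with no opposite-strand gene would be residual reads of the other orientation. Angptl4 and Cpt1a are among these genes. How well such residual reads follow the level of the transcript was not tested.

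The 61 genes lower with palmitic acid among those with no opposite-strand gene may follow the sense-to-opposite ratio rather than the treatment. Of them 100% (61 of 61, 95% exact interval 94.1% to 100%) were lower in control replicate 3, the control with the higher ratio, than in the mean of the other controls, beside 46.9% of all genes tested, and their median difference there was -1.34 on the log2 scale. Across all 12548 genes, control replicate 3 against the other controls moved like palmitic acid replicates 2 and 3 against palmitic acid + carnitine replicates 2 and 3 (Pearson r = 0.54, Spearman rho = 0.53), but less so across the 5920 genes with no opposite-strand gene (0.24 and 0.23), and genes are not independent replicates. Palmitic acid as the cause cannot be told apart from this: with the ratio as a covariate 0 of the 61 passed, their median fold going from -1.58 to -0.53 at a median SE of 0.35 and 0.34, so the smaller fold ended the calls, but 57.6% of the variance of the ratio lies between the groups, and without control replicate 3 and palmitic acid replicate 1 there were 59 that passed. A wrong label of control replicate 3 was not tested directly and stays open, and the control means include that library. Exchanging it with palmitic acid replicate 2 or 3 gave fewer calls among these genes, 29 and 23 against 65. Fewer calls alone do not exclude a wrong label.

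Angptl4 and other PPAR targets were higher with palmitic acid and lower with carnitine. Among genes with no opposite-strand gene, the list still rose with the sense-to-opposite ratio as a covariate (camera, adjusted p = 0.00914, median 0.35, 8 of 10 targets above 0). It fell there with carnitine (adjusted p = 0.0498), but the adjusted p of the rise became 0.52 with an estimated correlation. Angptl4 went there from 1.36 ± 0.23 to 1.17 ± 0.27 with the covariate and lost its call (adjusted p = 0.0720). The fold moved by less than its SE, the SE grew and the fit had 1 residual degree of freedom fewer. With the covariate across all genes the list lost its call in both palmitic acid contrasts. The ratio as the whole cause therefore stays open, and so does palmitic acid, under which 8 of 10 targets stayed higher without palmitic acid replicate 1 and all 10 without that library and control replicate 3. Adipocytes among the cells stay open too. Of 5 adipocyte genes (Adipoq, Cfd, Retn, Lep and Plin1) only Cfd is in the table. It had 0.336 CPM over the palmitic acid libraries (4 counts, all in replicate 1) and 3.27 in palmitic acid + carnitine replicate 2 (8 counts). Of the 15 listed markers 10 are in the table, 8 of them at no more than 43 counts over the palmitic acid libraries. Among these 8, raw counts in control, palmitic acid and palmitic acid + carnitine were 12, 43 and 9 for Pparg and 15, 38 and 14 for Lpl. They were 10, 5 and 16 for Cd36 and 0, 0 and 18 for Slc7a10. Cfd, Cidec, Adrb3 and Aoc3 had 8 or fewer in every group. Raw counts are not scaled for depth. Cebpa, opposite Gm45091, and Car3 leaned the same way as the PPAR targets without passing (log2 fold change 0.49 ± 0.28 and 0.18 ± 0.33 with palmitic acid, -0.49 ± 0.28 and -0.80 ± 0.34 with carnitine). Missing genes and genes near the floor exclude nothing.

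Other groupings of the same libraries show how far chance can be excluded. With 3 against 3 there are 10 splits, too few for a share under 0.05. edgeR called 0 genes in each contrast and 0 in the highest other split, so 10 of 10 splits gave as many in each. Lists called were 16 with palmitic acid against 13 in the highest other split (1 of 10 as many), 19 with carnitine against 10 (1 of 10), and 2 in the last contrast against 3 (3 of 10). Among genes with no opposite-strand gene calls were 65 against 29 (1 of 10), 66 against 0 (1 of 10) and 0 against 1 (10 of 10). The split with 29 exchanged control replicate 3 for palmitic acid replicate 2, and that with 23 exchanged it for palmitic acid replicate 3. For genes moved back, 100 groupings of the 9 libraries were drawn: 100 of 100 gave as many as the 0 among all genes, and among genes with no opposite-strand gene 1 of 100, the real one, gave 35, against 17 in the highest other. That share, in a gene set chosen after seeing the data, argues against chance in how the libraries were grouped and does not separate treatment from the ratio.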
